A study of Cereibacter sphaeroides with 7 samples.

How the data were processed

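Total RNA of 7 samples was hybridised to 1-colour arrays, and the 4 photosynthetic and 3 aerobic samples were grouped by their growth descriptions. The authors deposited 1 linear signal intensity per probe set and array, with no negative values. How this intensity was made is not given in the sources used here. The mean of the values between the lowest and highest 2% of each array was 998.0 to 998.6, from which a scaling of each array to about the same trimmed mean was inferred. Detection calls were not used here.

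Of 5355 probe sets, 3 were array controls and were left out, and other controls without a name may remain among the 5352 tested. The annotation named 539 probe sets, standing for 514 genes, and gave no name for 4813. For the 10 genes with several probe sets, the probe set with the highest mean over the 7 arrays stood for the gene. Values were log2(signal + 27.3), the added amount being 5% of the median array median, so that fold changes of dim genes are understated. Where signals lay below an array's 10th percentile (61.2 to 85.4), which was chosen after the values were seen and is not a measured background, a fold change with them raised to it is also given. The array medians spanned 0.39 on the log2 scale, above the limit of 0.2 set before the data were examined, so arrays were quantile normalized. Signals in the text are as deposited, and fold changes are from the normalized log2 values, photosynthetic minus aerobic.

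Fits used limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3 with statmod 1.5.0, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. In simulated data with the spread of these arrays, 5352 probe sets and 67, 67 and 66 of them changed, this fit recovered 11.9% of 1.5-fold, 49.3% of 2-fold and 83.3% of 4-fold changes, with 8 false calls. Far fewer probe sets were changed there than were called in the real comparison (1285), so these shares may not hold for it. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists of at least 3 measured genes. Camera compares a list with the other named genes, while fry, an alternative, tests only whether a list's genes move one way.

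The comparison, its test, 24 gene lists and the rule for named genes were fixed before the data were examined. That plan assumed product text and locus tags, which the annotation used here does not hold. Lists were therefore matched on gene symbols, and the ribosomal and motility lists on symbol stems set after the names, but before any test, were seen. Of the 24 lists 18 were tested. The other 6 had fewer than 3 genes. Calvin cycle genes had 1 of 2 called higher, nitrogen oxide and DMSO respiration 1 of 2, gas vesicles 1 of 1 and polyhydroxyalkanoate metabolism 0 of 1. No named gene matched the aa3 oxidase list or the list by locus range, and no probe set was marked as intergenic, so these were not analysed here. Measured genes of a list are those matched by name. Other members may be among the 4813 probe sets without a name. The rule named the 10 largest rises and 10 largest falls among named genes that passed, changed at least 2-fold and did not overlap between groups, up to 4 called genes of each list, all photosynthesis regulators, and up to 2 members per list that did not pass.

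Replicons were assigned through unique gene symbols in a RefSeq gene table of assembly ASM332471v1, which may differ from the genome behind the array, so no coordinates are given. Calls were compared between replicons with Fisher's exact test, two-sided. Genes of one operon are not independent, so this describes the calls.

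Alternatives were a pseudocount of 1% or 20%, removal of the dimmest 25% of probe sets, signals as deposited, equal array medians, eBayes without trend or robust, array weights, each array left out in turn, and camera with an estimated correlation or fry. Added after the data were seen were fits without aerobic replicates 1 and 3, without probe sets 5101 to 5250, and with the level of probe sets 5301 to 5350 as a covariate. Windows of 50 consecutive probe sets were searched for probe sets dim on a pair of arrays. The pair, the window and its neighbours on one side were chosen from the values. The test that shuffled probe-set order first scored windows by share, which let a short last window lead, and was changed to the number of dim probe sets after that fault was seen. The 35 splits of the arrays into 4 and 3 were counted for camera with the preset correlation first, and the count with an estimated correlation was added after that result was known.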

Results

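RNA levels of the purple bacterium Rhodobacter sphaeroides 2.4.1 (now Cereibacter sphaeroides) were measured on 1-colour oligonucleotide arrays, 1 array per sample. The bacterium can live by aerobic respiration in the dark or by photosynthesis in the light without oxygen. Cultures in Sistrom's minimal medium were grown photosynthetically at 10 W/m2 of light under 95% N2 and 5% CO2 (4 arrays), or aerobically in the dark under 30% O2, 69% N2 and 1% CO2 (3 arrays). Light, oxygen and CO2 therefore differ together between the growth modes. The labels do not state that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Each array gave a signal for 5355 probe sets, with array medians from 430.7 to 573.3, and the number of arrays limits the precision. Pearson's r between arrays, across probe sets, which are not independent replicates, was 0.94 to 0.964 among photosynthetic arrays, 0.935 to 0.976 among aerobic arrays and 0.83 to 0.87 between growth modes.

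The comparison asks which genes differ in RNA level between photosynthetic and aerobic growth. Measured genes of the photosynthetic apparatus were higher in the photosynthetic arrays, as were most measured flagellar genes, and all 9 measured genes of respiratory complex I were lower. Measured genes are those matched by name, and other members may be among the 4813 unnamed probe sets. The reaction centre gene pufM had a mean signal of 22508 ± 1489 (SD, n = 4) in photosynthetic arrays and 2057 ± 231 (SD, n = 3) in aerobic arrays. The flagellar rod gene flgG had 3330.2 ± 174 (SD, n = 4) against 84.1 ± 5.0 (SD, n = 3). In the other direction, hemF, which encodes the oxygen-dependent coproporphyrinogen oxidase, had 362 ± 33 (SD, n = 4) against 1797 ± 120.0 (SD, n = 3).

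Of 5352 probe sets tested with limma and Benjamini-Hochberg adjustment, 1285 changed at an adjusted p below 0.05, of which 577 were higher and 708 lower in photosynthetic arrays. At least 2-fold changes were called for 665 probe sets, 431 higher and 234 lower. Among 514 named genes, 85 rose and 74 fell, and 57 of those that rose and 16 of those that fell changed at least 2-fold. The count of calls was 828 without aerobic replicate 3. Of all calls, 44.9% were higher, against 54.5% with array medians made equal and 40.7% with signals as deposited, and the median log2 fold change of all probe sets was -0.14, -0.09 and -0.23 in these settings.

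All 11 measured genes of bacteriochlorophyll synthesis rose, with a mean log2 fold change of 2.76 (camera, adjusted p = 6.52e-12, and adjusted p = 0.0232 with an estimated correlation). The largest rises were those of bchZ, a subunit of chlorophyllide reductase, with a log2 fold change of 3.53 ± 0.16 (SE), bchF with 3.46 ± 0.15, bchB, a subunit of the dark-operative protochlorophyllide reductase, with 3.46 ± 0.18, and bchE, the oxygen-independent cyclase, with 3.39 ± 0.18. Their adjusted p-values from limma lay between 3.21e-07 and 8.71e-07. Mean signals of bchZ were 4840.4 ± 900.2 (SD, n = 4) and 421 ± 84.7 (SD, n = 3). The 5 probe sets of bchF gave log2 fold changes from 3.24 to 3.46.

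All 7 measured genes of the reaction centre and light-harvesting list rose too, by 2.50 on average (camera, adjusted p = 4.44e-08, and adjusted p = 0.0232 with an estimated correlation). Within this group pufQ rose by 3.37 ± 0.12 (SE), pufM by 3.31 ± 0.12, pufL by 2.79 ± 0.12 and pufX by 2.67 ± 0.16 on the log2 scale, with adjusted p-values of 9.07e-08, 8.02e-08, 3.21e-07 and 2.39e-06. pufL and pufM encode reaction centre subunits. The light-harvesting gene pufA, not named by the rule, rose least of the 7, by 1.28 ± 0.18 (limma, adjusted p = 0.000736). Its 5 probe sets lay between 1.25 and 1.79. The 4 measured carotenoid genes all rose, with a mean of 1.57 (camera, adjusted p = 0.00171, but adjusted p = 0.138 with an estimated correlation). Log2 fold changes were 2.53 ± 0.13 (SE) for crtA, 1.75 ± 0.15 for crtB, 1.12 ± 0.22 for crtC and 0.86 ± 0.24 for crtD. The call of crtD (adjusted p = 0.029) was lost without each of 4 of the 7 arrays in turn, photosynthetic replicates 1 and 2 and aerobic replicates 1 and 3, with adjusted p-values up to 0.083.

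**Figure D1:**
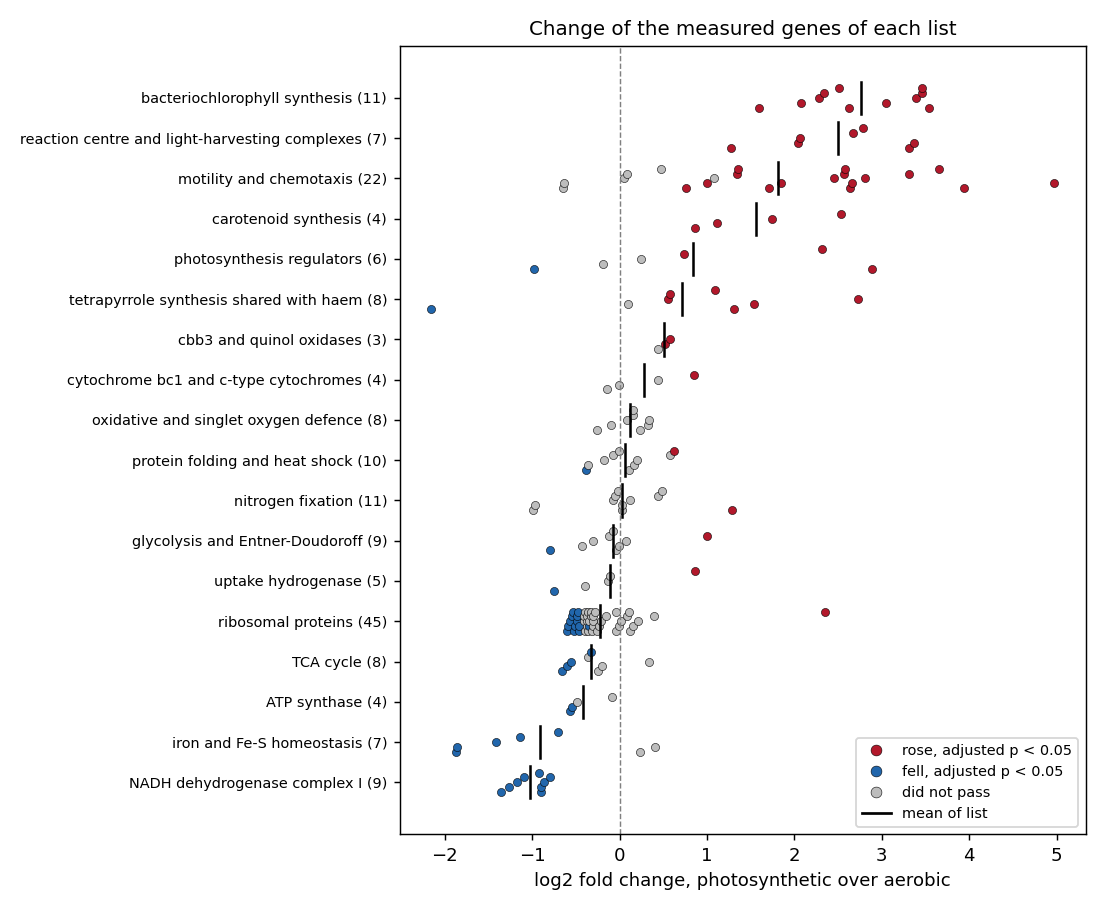
Log2 fold change (photosynthetic over aerobic, horizontal axis) of each measured gene in the 18 lists tested, with the number of genes in brackets, 1 point per gene and a vertical bar at each list's mean. All 11 bacteriochlorophyll genes lie to the right of 0 and all 9 complex I genes to the left, while the ribosomal mean of -0.22 was 0.04 with signals as deposited and 0.18 with array medians made equal.

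Of 8 measured genes of tetrapyrrole synthesis, the pathway shared by haem and bacteriochlorophyll, 6 rose, 1 fell and 1 did not pass (camera, adjusted p = 0.00878, but adjusted p = 0.103 with an estimated correlation). The oxygen-independent coproporphyrinogen oxidase gene hemN rose by 2.73 ± 0.10 (SE) on the log2 scale (adjusted p = 1.05e-07), whereas hemF fell by 2.16 ± 0.18 (adjusted p = 2.2e-05). hemA, which encodes 5-aminolevulinate synthase, rose by 1.53 ± 0.12 (adjusted p = 1.65e-05). Its isozyme gene hemT was called at 1.31 ± 0.42 (adjusted p = 0.049), and this call was lost without each array in turn except photosynthetic replicate 1, with adjusted p-values up to 0.149, and under both other scalings, and its aerobic signals were below the 10th percentile of all 3 arrays. With signals below that percentile raised to it, hemT was at 1.07. HemH, ferrochelatase, did not pass, with a log2 fold change of 0.10 ± 0.12 (adjusted p = 0.595).

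**Figure D2:**
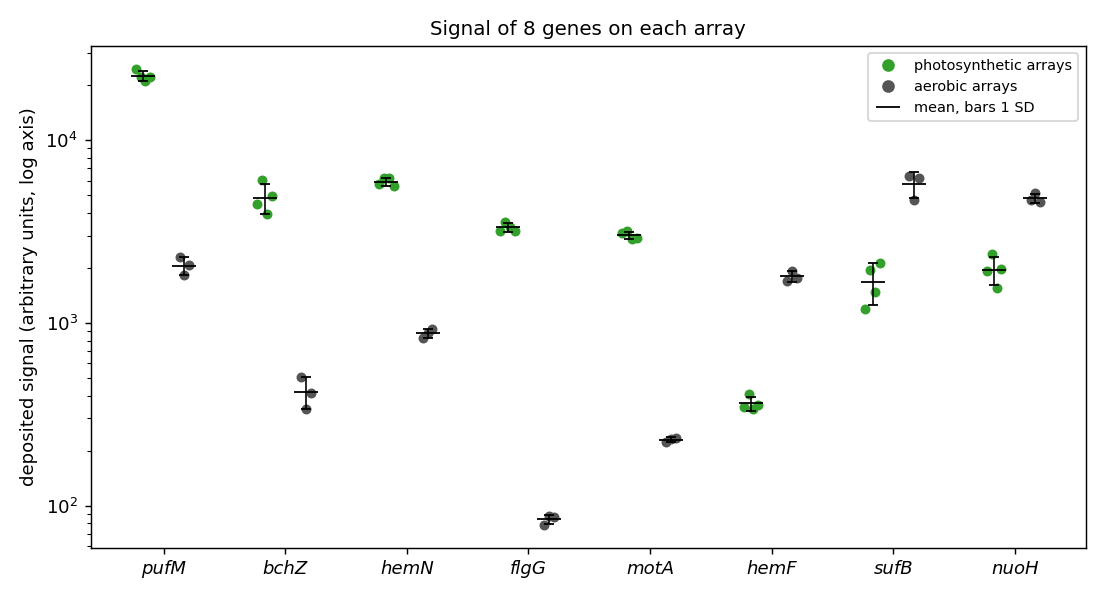
Deposited signal (arbitrary units, log axis) of 8 genes on each of the 4 photosynthetic and 3 aerobic arrays, with horizontal marks at group means and bars of 1 SD. The groups do not overlap for these genes, which for all but hemN was a condition for being named among the largest changes. Means were 5928 against 875 for hemN and 362 against 1797 for hemF.

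Among 6 photosynthesis regulators 3 rose, 1 fell and 2 did not pass, and the list as a whole did not pass (camera, adjusted p = 0.113). Log2 fold changes were 2.89 ± 0.13 (SE, adjusted p = 3.22e-07) for tspO, an outer membrane protein that affects pigment gene expression, and 2.32 ± 0.16 (adjusted p = 6.44e-06) for ppaA, and appA, the antagonist of the repressor PpsR, rose by 0.73 ± 0.16 (adjusted p = 0.00845), the highest of its 5 probe sets, of which 4 were called and the lowest was at 0.46. The gene of the anaerobic regulator FnrL fell by 0.98 ± 0.14 (adjusted p = 0.000652), and its 5 probe sets lay between -1.12 and -0.90. Neither ppsR, at -0.18 ± 0.16 (adjusted p = 0.45), nor the sensor kinase gene prrB, at 0.24 ± 0.15 (adjusted p = 0.274), passed. The 5 probe sets of ppsR lay between -0.18 and 0.39 with 0 called, so they give no direction.

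All 9 measured genes of NADH dehydrogenase complex I fell, with a mean log2 fold change of -1.03 (camera, adjusted p = 3.54e-06, but adjusted p = 0.0877 with an estimated correlation). Examples are nuoH at -1.36 ± 0.14 (SE), nuoG at -1.27 ± 0.10, nuoL at -1.17 ± 0.10 and nuoE at -1.09 ± 0.14, with adjusted p-values up to 0.000499. Mean signals of nuoG were 1393 ± 67.7 (SD, n = 4) and 3364 ± 114 (SD, n = 3). Of 3 measured cbb3 oxidase genes, ccoN at 0.58 ± 0.12 and ccoP at 0.52 ± 0.11 rose, and ccoO at 0.44 ± 0.14 missed the threshold over all probe sets, although all 3 rose when adjusted over the list alone (camera, adjusted p = 0.0548). With signals as deposited and with array medians made equal ccoO passed (0.64, adjusted p = 0.0144, and 0.78, adjusted p = 0.0285). The cbb3 list passed with signals as deposited (adjusted p = 0.0311), without photosynthetic replicate 3 (0.036) and without aerobic replicate 1 (0.0458). It did not pass with camera's estimated correlation (adjusted p = 0.368). The cytochrome c2 gene cycA rose by 0.85 ± 0.16 (adjusted p = 0.00344), the only call in a list of 4 whose other members are the cytochrome c maturation genes ccmA, ccmB and ccmD (camera, adjusted p = 0.431). No bc1 gene was matched by name. The size of these rises depends on the scaling. Under the other scalings cycA was at 1.15 and 1.29, ccoN at 0.72 and 0.86 and ccoP at 0.66 and 0.80. The iron and Fe-S list had 7 measured genes, of which 5 fell and 2 did not pass (camera, adjusted p = 0.0307, but adjusted p = 0.286 with an estimated correlation). This list missed the threshold without photosynthetic replicate 1 (adjusted p = 0.0589) and without aerobic replicate 2 (adjusted p = 0.0631). The Fe-S assembly genes SufC and sufB fell by 1.87 ± 0.20 and 1.86 ± 0.22, and exbD and exbB, of the energy-transducing system for TonB-dependent uptake, by 1.41 ± 0.13 and 1.14 ± 0.19.

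Flagellar and motor genes, with no chemotaxis gene among them, numbered 22, of which 16 rose, none fell and 6 did not pass, and 18 rose when adjusted over the list alone (mean log2 fold change 1.82, camera, adjusted p = 8.78e-10, and adjusted p = 0.0232 with an estimated correlation). The largest changes were 4.97 ± 0.13 (SE) for flgG, 3.94 ± 0.23 for flgH, 3.65 ± 0.11 for the motor gene motA and 3.31 ± 0.25 for fliE, with adjusted p-values of 1.77e-08, 2.12e-06, 4.19e-08 and 1.33e-05. Aerobic signals of flgH and fliE lay below the array's 10th percentile on 3 and 2 of 3 arrays, so their fold changes depend on the pseudocount, and with those signals raised to that percentile they were 3.11 and 2.98. The aerobic mean of flgG, 84.1, was close to that percentile (71.3 to 85.4 on aerobic arrays), so its fold change depends on the pseudocount too. The probe sets of fliM disagreed, at 0.08 and 3.51, and the brighter, which stands for the gene, did not pass. The only members below 0 were flbT at -0.65 ± 0.28 and flaF at -0.64 ± 0.35, neither called (limma, adjusted p = 0.126 and 0.225). Both were placed on a plasmid.

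The 45 ribosomal protein genes had a mean log2 fold change of -0.22 and a median of -0.34, with 13 called lower, 1 called higher and 31 not passing (17 lower when adjusted over the list alone, camera, adjusted p = 0.000965, but adjusted p = 0.343 with an estimated correlation). Their direction depends on the scaling, since the mean was 0.04 with signals as deposited (adjusted p = 0.994) and 0.18 with array medians made equal (adjusted p = 0.814). The calls of rplX at -0.60 ± 0.15 (SE), rpsO at -0.59 ± 0.17 and rpmD at -0.56 ± 0.15 ended in both of these settings. In contrast, rpmH rose by 2.35 ± 0.29 (adjusted p = 0.000326), and its lowest value over the scalings was 2.35. Of 8 genes of the TCA cycle, 4 fell over all probe sets and 5 when adjusted over the list alone (camera, adjusted p = 0.0438, but adjusted p = 0.274 with an estimated correlation), with values of -0.66 ± 0.12 for gltA, -0.60 ± 0.10 for sucD, -0.55 ± 0.17 for mdh and -0.33 ± 0.10 for 1 of 2 genes named sdhA (the other, at -0.20 ± 0.19, did not pass). With array medians made equal the list mean was -0.14 (adjusted p = 0.217), and none of these 4 genes passed. The list was also lost with signals as deposited (adjusted p = 0.0923), without trend (0.0609), with array weights (0.0677), and without photosynthetic replicate 1, aerobic replicate 1 and aerobic replicate 2 (adjusted p = 0.0589, 0.0722 and 0.0671). The calls of mdh and sdhA ended as deposited (adjusted p = 0.105 and 0.173) and without 4 and 5 of the 7 arrays in turn (up to 0.17 and 0.109). The 4 ATP synthase genes are 2 named atpD and 2 named atpA, and 1 of each was called lower, at -0.57 ± 0.16 and -0.54 ± 0.16 (camera, adjusted p = 0.191). The others, at -0.48 ± 0.20 and -0.09 ± 0.19, did not pass (adjusted p = 0.122 and 0.776). Neither call held with signals as deposited (-0.37, adjusted p = 0.128, and -0.23, adjusted p = 0.34), with array medians made equal (-0.23, adjusted p = 0.508, and -0.09, adjusted p = 0.822), without trend (adjusted p = 0.0654 and 0.0618) or without 5 of the 7 arrays in turn (up to 0.126 and 0.134).

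In the remaining lists few genes passed. Of 11 nitrogen fixation genes only the activator gene nifA rose, by 1.28 ± 0.21 (SE, adjusted p = 0.00196), and nifH was at 0.02 ± 0.21 (adjusted p = 0.947, list camera adjusted p = 0.813). For 5 hydrogenase accessory genes, all hyp symbols, hypA was called higher at 0.86 ± 0.27 (adjusted p = 0.0485) and hypF lower at -0.75 ± 0.17 (adjusted p = 0.0101, list adjusted p = 0.664). Aerobic signals of hypA were below the 10th percentile on 2 of 3 arrays, and with them raised to it the log2 fold change was 0.61. The gene hypA did not pass with signals as deposited (0.73, adjusted p = 0.119), with array medians made equal (0.87, adjusted p = 0.054), with a 1% pseudocount (adjusted p = 0.0562), with robust fitting (0.0673), with array weights (0.0758) or without 5 of the 7 arrays in turn (up to 0.157), nor did hypF without aerobic replicate 3 (adjusted p = 0.0627). Of 9 genes of glycolysis and the Entner-Doudoroff pathway, edd was called higher at 1.00 ± 0.24 and pfkB lower at -0.80 ± 0.18 (list adjusted p = 0.635), and both missed the threshold without aerobic replicate 3 (adjusted p = 0.0581 and 0.0674), as did edd without aerobic replicate 1 (adjusted p = 0.0633). Among 10 genes of protein folding and heat shock, dnaK was called higher at 0.62 ± 0.19 and lon lower at -0.38 ± 0.11 (list adjusted p = 0.816), each lost without 5 of the 7 arrays in turn, with adjusted p-values up to 0.111 and 0.144, and without trend (0.0744 and 0.0931). The call of lon was also lost with signals as deposited (-0.32, adjusted p = 0.0782) and with array medians made equal (-0.18, adjusted p = 0.432). None of 8 genes of oxidative and singlet oxygen defence passed limma's threshold, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.601).

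Of the named genes, 447 could be placed on a replicon. Those called were 119 of 406 on chromosome 1, 8 of 32 on chromosome 2 and 3 of 9 on the plasmids. No replicon's share differed past the threshold, with a lowest adjusted p of 0.857 in Fisher's exact test. The plasmid share rests on 9 genes, so it cannot decide whether plasmid genes were called more often. The called genes traL, trbC, traF, repB and 1 gene named repA were not placed and are not counted in it. Among the 10 largest falls named by the rule, which leaves out genes that overlap between groups, 1 other was mscL, a mechanosensitive channel gene, at -1.83 ± 0.22 (SE). The rest were 1 of 2 genes named cysE, for serine acetyltransferase, at -1.36 ± 0.22 (the other, at -0.24 ± 0.18, did not pass, with adjusted p = 0.378), and selD, the selenophosphate synthetase gene, at -1.16 ± 0.24. Of the 20 largest fitted rises 1 had a gene name, and none of the 20 largest fitted falls did. Probe sets 4218 and 896 rose to mean signals of 5805 ± 1248 and 2449 ± 953 (SD, n = 4) from aerobic signals below the 10th percentile of all 3 arrays, where no exact fold can be given. With those signals raised to that percentile, the log2 fold changes were 5.82 and 4.57. Unnamed probe sets 3922 and 2746 were lower by log2 fold changes of -3.28 ± 0.26 and -3.18 ± 0.22.

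Aerobic replicates 1 and 3 differed from aerobic replicate 2 in a run of consecutively numbered probe sets, 5101 to 5250. Of these 150 probe sets, 41 were, after normalization, more than 2-fold below the lowest of the other 5 arrays on both aerobic replicates 1 and 3. The median signal of those 41 was 89.1 on aerobic replicate 1, 81.8 on aerobic replicate 3, 773 on aerobic replicate 2 and 1286 to 1523 on the photosynthetic arrays. Between growth modes, 79 of the run's 150 probe sets were called, against 1285 of all 5352. Without aerobic replicates 1, 2 and 3 in turn, 60, 85 and 55 were called. Aerobic replicate 2 was also lower than the photosynthetic arrays there, with a median log2 difference of -0.495 in the run and 0.11 elsewhere. For aerobic replicates 1 and 3 the median in the run was -1.36. Over all probe sets, aerobic replicate 2 was the less similar aerobic array. Its r was 0.935 with replicate 1 and 0.944 with replicate 3, against 0.976 between replicates 1 and 3. Its highest signal was 135994, against 59786 on replicate 1 and 57697 on replicate 3.

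**Figure D3:**
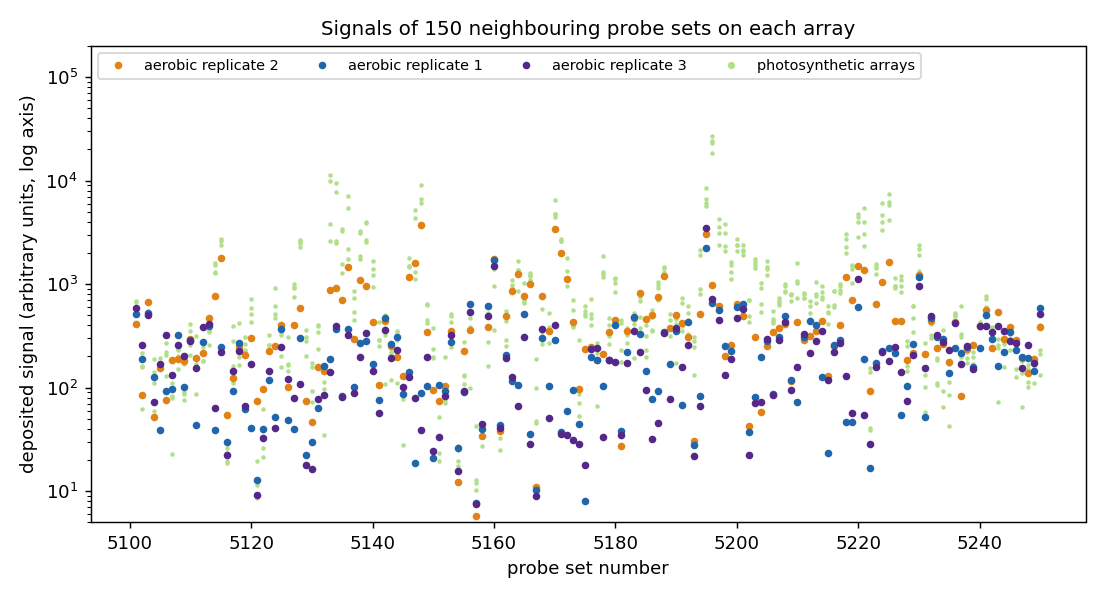
Deposited signal (arbitrary units, log axis) of probe sets 5101 to 5250 on each array, 1 point per probe set and array. Aerobic replicates 1 and 3 lie below aerobic replicate 2 for many probe sets, with medians over the run of 178, 172 and 344.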

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

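The expectation for every test in this part, the split counts included, was written after the results were seen. In 1 of the 35 splits of the 7 arrays into 4 and 3, the real one, 1285 probe sets passed, and the highest of the other splits gave 3. This argues against chance in the grouping of arrays but cannot exclude it, because 1 of 35 is the smallest share possible. Every other split also mixes the growth modes, which by itself lowers its count. The same holds for changes of at least 2-fold, with 665 probe sets in the real split, 3 in the highest other and 1 of 35 splits as large. For the number of gene lists past the threshold with camera's preset correlation, 9, chance cannot be excluded, since 4 of 35 splits gave as many and the highest other split also gave 9. With an estimated correlation the real split gave 3 lists and the highest other 0, in 1 of 35 splits, a count added after the preset one was known. For replicons the real count was 0, which all 35 of 35 splits must reach, so this comparison carries no information.

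Of 82 items tested for 1 photosynthetic array standing apart, 2 stood out, and chance alone gives about 4.1. On the normalized scale the gap of ftsH in photosynthetic replicate 1 to the nearest of the others was 0.955 of the range (5240 against deposited signals of 4334 to 5076). These deposited signals show no gap of that size. For fliM the gap on the normalized scale was 0.947 in photosynthetic replicate 2 (deposited signals of 1381 against 2713 to 2790.1).

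Probe sets 5101 to 5250 were dim on aerobic replicates 1 and 3. A difference in scaling is argued against, because 27.3% of the run's probe sets were dim on these arrays alone even under the scaling with the lowest share, against at most 0.596% elsewhere. Chance placement is also argued against, since in 0 of 10000 shuffles of the probe-set order did a window hold as many dim probe sets as the 17 seen, the highest being 7, although the pair of arrays was picked from all pairs and the shuffles do not allow for that. Whether DNA carrying the run, such as a plasmid, may have been missing from these cultures stays open: 6 of the run's 150 probe sets were above the array median on both arrays. The gene traU of the run was placed on a plasmid. Its signals on aerobic replicates 1, 2 and 3 were alike, at 497, 412 and 429. Of the 41 dim probe sets at least 34.1% lay below the 10th percentile but at least 85.4% below the 25th, so the answer depends on the level taken as background.

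Probe sets 5301 to 5350 differed between arrays of one growth mode, with mean log2 levels of 9.26, 11.52 and 9.61 on aerobic replicates 1 to 3 and 10.12 to 10.86 on photosynthetic arrays. With this level as a covariate 1242 probe sets passed. The aerobic levels lay on both sides of the photosynthetic ones, so the level does not follow the growth mode and could change the calls little. This count therefore cannot decide whether the difference lies behind calls between growth modes. The source of the difference was not tested. Among aerobic arrays replicate 2 stood apart here, with 68% of probe sets 5301 to 5350 counted as above every other aerobic array. The next highest window for that array had 36%.

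The mean level of the motility list was higher in every photosynthetic array (9.81 to 9.85 on the log2 scale) than in every aerobic array (7.85 to 8.20). Neither scaling nor a single array accounts for it, because the list's mean log2 fold change was at least 1.71 over the 3 scalings and at least 1.75 without each array in turn. The gap between the nearest arrays was 1.6, and a difference between stocks of the strain cannot be told apart from the growth mode, since the labels do not link arrays to stocks. Array titles differ in form within each growth mode but name no stock. An effect of light, oxygen or CO2 on motility genes may be the source, as a hypothesis that this design cannot split.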

How the results depend on the processing

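Fits without aerobic replicates 1 and 3 together, without probe sets 5101 to 5250, and with the covariate were chosen after seeing the data. No paired analysis was possible because replicate numbers only follow the order of deposit. The count of 1285 calls was 828 to 1195 without each array in turn, lowest without aerobic replicate 3, and 516 without aerobic replicates 1 and 3, which leaves 4 arrays against 1 assumed to vary alike. Of those 516, 477 were among the 1285. Higher calls were 341 in that fit, at least 2-fold lower calls 139, and lower calls 175, against 381 to 655 without single arrays (428 without aerobic replicate 1, 381 without aerobic replicate 3). Fewer arrays lower these counts by construction. Without probe sets 5101 to 5250, 1207 passed. The 9 lists became 3 with an estimated correlation and 14 with fry, which tests another question, and were 7 to 10 without each array. Camera was not run with robust eBayes, which it does not use. Lists without a call that turned were nitrogen fixation, at -0.12 as deposited, 0.024 with equal medians (camera turned, not the mean), -0.083 without aerobic replicates 1 and 3 and -0.076 to 0.083 without single arrays (-0.042 without aerobic replicate 3), protein folding, -0.020 to 0.121 without single arrays (lowest without aerobic replicate 2), and oxidative defence, at 0.029 without aerobic replicates 1 and 3 (again camera, not the mean). The ribosomal list, called lower, turned to 0.18 with equal medians, and its mean, not camera's direction, to 0.04 as deposited. Genes that turned were not called: nifH, at -0.17 as deposited, -0.029 with equal medians, -0.18 without aerobic replicates 1 and 3, -0.039 with the covariate and -0.090 to 0.126 without single arrays (-0.034 without photosynthetic replicate 2, lowest without aerobic replicate 1), and fliM, -0.070 to 0.313 without single arrays (-0.0071 without photosynthetic replicate 3, lowest without aerobic replicate 2). The cause was not tested. Called genes named here, prrB, HemH, ccoO and ftsH kept their direction in these fits, except that pufA was not followed in them. The probe set standing for ppsR kept its direction too, but the probe sets of ppsR differ in sign and give no direction. Of 55 called genes named by the rule, 40 stayed called without each array and 15 did not, and 12 were lost under another scaling. Signal over background limits dim genes, and no background level was used here.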

Other observations

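The genes in this part were chosen after their values were seen. Outside the lists, dksA, a regulator of the stringent response, rose by 2.78 ± 0.20 (SE) on the log2 scale, from a mean signal of 571 ± 156 (SD, n = 3) to 3874 ± 636 (SD, n = 4) (limma, adjusted p = 9.91e-06). The rubisco activase gene cbbX rose by 1.86 ± 0.15 (adjusted p = 1.66e-05), and a gene named fusA, for elongation factor G, by 1.85 ± 0.13 (adjusted p = 6.46e-06). The xylose genes xylA and xylF fell by 1.10 ± 0.17 and 1.08 ± 0.14 (adjusted p = 0.00115 and 0.000411). Of 10 genes with symbols beginning in cob, of cobalamin synthesis, 6 rose and none fell, but the group did not pass (camera, adjusted p = 0.171).

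Conjugation genes trbC and traL rose by 2.65 ± 0.20 and 2.61 ± 0.17 (limma, adjusted p = 1.28e-05 and 5.14e-06), and traF and traU by 1.57 ± 0.33 and 1.13 ± 0.15. All 4 lie among probe sets 5101 to 5250, but traL (568, 608 and 449.5 on aerobic replicates 1, 2 and 3), trbC (117, 117 and 94.0) and traU (497, 412 and 429) had like signals on the aerobic arrays and were not dim on replicates 1 and 3 alone. Signals of traF were 126, 439 and 351, and its call held without each single array (highest adjusted p = 0.0258). Its log2 fold change was 0.99 with aerobic replicate 2 as the only aerobic array. The plasmid replication genes repA (1 of 2 genes of that name, the other at 0.25 ± 0.15 and not called) and repB, also there, were called at 2.39 ± 0.76 and 1.95 ± 0.55 (adjusted p = 0.0492 and 0.0296). Signals on aerobic replicates 1, 2 and 3 were 106, 1257 and 66.6 for repA (2.33 with the last raised to the array's 10th percentile) and 116, 852 and 127 for repB, against photosynthetic signals of 855 to 1658 and 874 to 1097. Both calls were lost without each array in turn except aerobic replicate 2, with adjusted p-values up to 0.178 and 0.123. Without aerobic replicate 2 the log2 fold changes were 3.60 for repA and 2.83 for repB. The lowest for repA was 1.64, without aerobic replicate 3, and repB was at 1.52 without aerobic replicate 1 and slightly lower without aerobic replicate 3. With aerobic replicate 2 as the only aerobic array they were 0.03 and 0.22, so both calls rest on aerobic replicates 1 and 3.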
